A study of Arabidopsis thaliana with 18 samples.

How the data were processed

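Small RNAs recovered with AGO1DAH, a slicer-defective AGO1 fused to GFP, were read from 18 libraries, 3 for each of 6 promoters (SPCH, EPF2, MUTE, FAMA, EPF1 and ML1). The labels state leaves of Col-0 seedlings aged 6 days, anti-GFP beads and small RNA libraries. The promoters were grouped into stages as the cell type labels give them. The labels do not say whether the libraries of a promoter came from separately grown plants, so p-values measure only the spread between these libraries.

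The deposited values are entered here as signal: the authors gave reads per 1000000 reads of the library (RPM), whole reads per row divided by a library total. Every value above 0 was a whole number of reads at 1 library total (100% of values within 0.01 read), which gave totals of 3116639 to 7339323 reads. The columns sum to 1.78 to 3.97 times 1000000 RPM, so reads entered more than 1 row. Overlapping rows and reads with several positions would both do this, and the share of each was not determined. Reads were aligned with Bowtie to TAIR10 and counted with bedtools, per the submitters' processing notes. The annotation, strand handling, length filter and treatment of reads with several positions were not given in the sources used here. Rows of a family, of paralogs and of overlapping or antisense genes can therefore share reads and were read as uncertain. The share of miRNA reads sums the highest row of each family, so that a read shared within a family enters once, and is a lower bound where a family has several distinct small RNAs. Rows without a name (502) were left out, which left 33852.

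Values were put on a log2 scale after adding 1 RPM. Rows with at least 1 RPM in at least 3 of 18 libraries were tested: 273 of 427 miRNA rows and 10670 of all rows. A single linear model with 6 group means was fitted with limma 3.58.1 in R 4.3.3, with empirical Bayes moderation and a mean-variance trend, and p-values were two-sided and adjusted by the Benjamini-Hochberg method within each comparison, with a threshold of 0.05. The comparisons were an F test over the promoters, each lineage promoter against ML1, the mean of the 5 lineage promoters against ML1, the 3 pairs of stages, and the promoters within entry and within differentiation. The model, the comparisons, the lists and the rule for naming rows were chosen before the data were examined. Because the miRNA share differed between libraries, each count is also given after median-ratio scaling over the 200 miRNA rows above 0 in every library. edgeR 4.0.16 was run on the recovered reads with the library totals and, chosen after seeing the data, with TMM factors. The design assumed RPM of distinct reads; the counting of reads in more than 1 row was found in the values.

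Named miRNAs were the 10 largest changes in each direction (lineage against ML1, differentiation against entry) or the 5 largest (other comparisons) past the threshold whose values did not overlap between the sides for at least 1 promoter. Chance gives this in 10% of splits of 3 against 3. In the lineage against ML1 any of 5 promoters could meet the rule, so chance gives it more often there. Where none passed, the 3 smallest p values were named, and the F test gave the 10 smallest. miR824 was followed throughout. Rows of a miRNA family with equal values in every library were named once. For rows other than miRNAs the 5 largest in each direction were named in 2 comparisons, without joining equal rows. Members of lists named as examples were those with the smallest p in a called list, and SCPL54, AGO1, SPL3 and the row upstream of MUTE were looked at in all promoters only after their values were seen.

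Lists of families were tested with limma's camera at a preset correlation of 0.01 and again with an estimated correlation: conserved families (119 rows), other families (154), leaf development (68), auxin signalling (19), phosphate and sulfate (12), copper (10), small RNA machinery (11), triggers of secondary siRNA (16), miRNAs bound by AGO7 or AGO10 (17) and phloem (16). MYB regulators had 2 rows and were not tested. TAS loci and markers of the stomatal lineage, guard cells, epidermis, mesophyll, phloem and trichomes were read from the fit of all rows. Library composition was compared by exact two-sided permutation tests, adjusted over 44 tests. Positions came from the TAIR10.1 annotation by name: all 427 miRNA rows had a position, and 32658 rows matched a reference locus. Floors of 3 reads cover counting error only.

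The steps were tested on simulated data made from these libraries, with MUTE set against ML1. Of 273 simulated miRNA rows, 50 were changed and 268 passed the filter: 5.88% of those changed 2 times, 11.8% of those changed 4 times and 56.3% of those changed 8 times were called, with 1 false call in 223 unchanged rows. Of 10670 simulated rows of all kinds, 200 were changed and 9650 passed the filter: 1.49, 14.9 and 47.0% of the changed were called, with 4 false calls in 10470 unchanged rows. A list shifted 2 times was called (camera adjusted p 8.1e-06), and 0 of 50 tests of unchanged lists were. Small changes would thus mostly be missed at this depth and number of libraries. The simulated rows were drawn independently of each other, without reads shared in a family and without differing miRNA shares. The false calls of rows and lists in the simulation therefore do not show how often false calls arise in these libraries.

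Alternatives were scaling (miRNA total, median ratio, quantiles), the pseudocount, the filter, the trend, array weights, edgeR, means of the log2 values over the rows of a family, only the groups compared, adjustment over all rows, the runs of sample numbers as a replicate block, each library left out in turn, and an added minimum change. TMM scaling in edgeR, leaving out the third run of sample numbers, median-ratio scaling with a pseudocount of 5, and permutation of the miRNA share and regrouping of libraries within replicate number were added after seeing the data.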

Results

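Small RNAs bound to AGO1 were sequenced from 18 libraries of Arabidopsis thaliana, made from leaves of Col-0 seedlings aged 6 days. AGO1 is the Argonaute protein that carries most plant microRNAs (miRNAs) to their target RNAs. A slicer-defective AGO1 fused to GFP (AGO1DAH) was expressed under 1 of 6 promoters and recovered with anti-GFP beads, and its small RNAs were sequenced. By the labels, the SPCH and EPF2 promoters mark entry into the stomatal lineage, MUTE marks commitment, FAMA and EPF1 mark differentiation, and ML1 marks the epidermis. Each promoter had 3 libraries. The authors' values were reads per 1000000 (RPM). Library totals recovered from the values were 3116639 to 7339323 reads, the lowest in MUTE replicate 3 and the highest in FAMA replicate 2. A single read therefore stood for 0.136 to 0.321 RPM, and a row listed at 0 allowed up to 0.409 to 0.963 RPM, which is 3 reads. Of 33852 named rows, 427 were mature miRNAs, and 252 to 355 of these were above 0 in a library. The tests covered the 273 miRNA rows with at least 1 RPM in at least 3 libraries.

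Reads of miRNA rows, counted as the highest row of each family so that shared reads entered once, made up 65.5% ± 4.94 (SD, n = 3) of the library in ML1 and 51.2% ± 11.4 in SPCH. Their share was 37.2% ± 14.0 in EPF2, 11.2% ± 4.59 in MUTE, 26.8% ± 19.2 in FAMA and 31.0% ± 20.2 in EPF1 (SD, n = 3 each). The 15 lineage libraries averaged 31.5% ± 18.5 (SD), and their difference from ML1 had an exact two-sided permutation p of 0.00368 (smallest possible 0.00123, adjusted p 0.162 over 44 tests of library composition). MUTE lay below the 6 entry libraries (44.2% ± 13.8, SD) with an exact permutation p of 0.0119, the smallest possible with these numbers (adjusted p 0.175). Differentiation (28.9% ± 17.8, SD, n = 6) had an exact permutation p of 0.128 against entry and of 0.167 against MUTE when replicate number was ignored. By replicate number, the shares were 64.3, 61.3 and 71.0% in ML1, 43.8, 45.6 and 64.3% in SPCH, and 33.0, 25.8 and 52.8% in EPF2. They were 8.45, 8.63 and 16.5% in MUTE, 20.9, 11.2 and 48.2% in FAMA, and 8.73, 36.1 and 48.2% in EPF1, so replicate 3 was highest in all 6 promoters. The labels do not say whether replicates of the same number were handled together. Permuted only within replicate number, a test chosen after the values were seen, the exact p was 0.0370 for differentiation against entry and 0.111 against MUTE. It was 0.0370 for MUTE against entry and 0.00463 for the lineage against ML1, each the smallest possible there, without adjustment for these 4 tests. Summed tRNA rows had 70.1 ± 35.3 kRPM (1 kRPM is 1000 RPM) in ML1, 718 ± 565 in SPCH, 301 ± 66.0 in EPF2, 1726 ± 632 in MUTE, 1628 ± 1225 in FAMA and 619 ± 215 in EPF1 (SD, n = 3 each), which was not the inverse order of the miRNA shares. Reads that entered several rows count several times in such sums, whose means pass the library total in MUTE and FAMA. The sums are therefore not shares of reads. Rows of the chloroplast genome summed to 18.7 ± 1.67 kRPM in ML1 (SD, n = 3) and 271 ± 177 in the lineage libraries (SD, n = 15; exact permutation p = 0.0245, adjusted p 0.180).

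**Figure D1:**
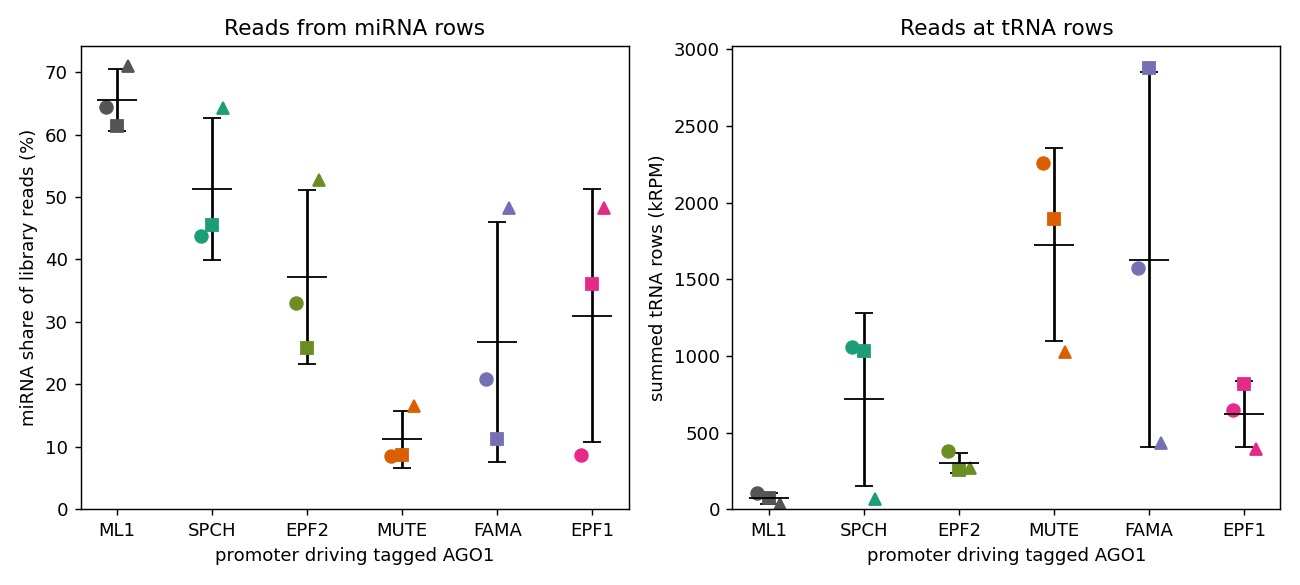
The left panel plots the share of library reads in miRNA rows (%) and the right panel the summed tRNA rows (kRPM) for the 6 promoters; symbols are the 3 libraries of a promoter and bars the mean ± SD. The 3 ML1 libraries lie between 61.3 and 71.0% miRNA reads and the 3 MUTE libraries between 8.45 and 16.5%. The tRNA sums count a read in every row it entered and are not shares of reads.

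The highest miRNA rows were those of the miR166 family, which targets HD-ZIP III transcription factors of leaf polarity. Averaged over the 18 libraries, miR166g had 80835 RPM, miR166e-3p 80776 and miR166f 80775. In miR166g the mean was 135128 ± 23894 RPM in ML1 and 20756 ± 4513 in MUTE (SD, n = 3). miR161.1 and miR161.2, which target PPR genes, held equal values in every library and averaged 49692 RPM. Their mean was 82781 ± 29853 RPM in ML1, 93479 ± 21051 in EPF2 and 9872 ± 8166 in FAMA (SD, n = 3). miR162b-3p, from the family that targets DICER-LIKE1, averaged 45591 RPM. On log2 values of the tested miRNA rows, a library correlated on average at 0.970 to 0.993 with the others of its promoter and at 0.937 to 0.967 with those of other promoters, across rows, which are not independent replicates. The first principal component held 61.1% of the variance and the second 16.1%. Within each lineage promoter, libraries with a higher miRNA share lay lower on the first component. EPF1 replicates 1 to 3, for example, lay at 22.9, -2.04 and -10.9. The ML1 libraries did not follow this order.

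Which miRNAs differed among the 6 promoters was asked with limma's moderated F test. The smallest adjusted p values were those of miR845a (1.5e-08), miR391-5p (1.9e-07), miR167c-3p (1.9e-07), miR319c (1.5e-06) and miR826a (3.4e-06). miR827 (7.0e-06), miR164a (1.2e-05), miR164c-5p, miR833a-5p and miR164b-5p (1.6e-05 each) followed in limma's adjusted p. miR845a, which pairs with the primer binding site of retrotransposons, had 9519 ± 2763 RPM in ML1, 11412 ± 2774 in SPCH and 161 ± 59.1 in FAMA (SD, n = 3). miR826a, which targets the glucosinolate gene AOP2, had 4.16 ± 2.85 RPM in ML1 and 0.101 ± 0.175 in SPCH (SD, n = 3), and was listed at 0 in the other four promoters. Of 273 rows, 157 passed an adjusted p of 0.05 (163 at an unadjusted p under 0.05), and 172 passed after median-ratio scaling. edgeR called 142 on the library totals and 164 with TMM scaling, and 126 rows were called by limma under both scalings.

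**Figure D2:**
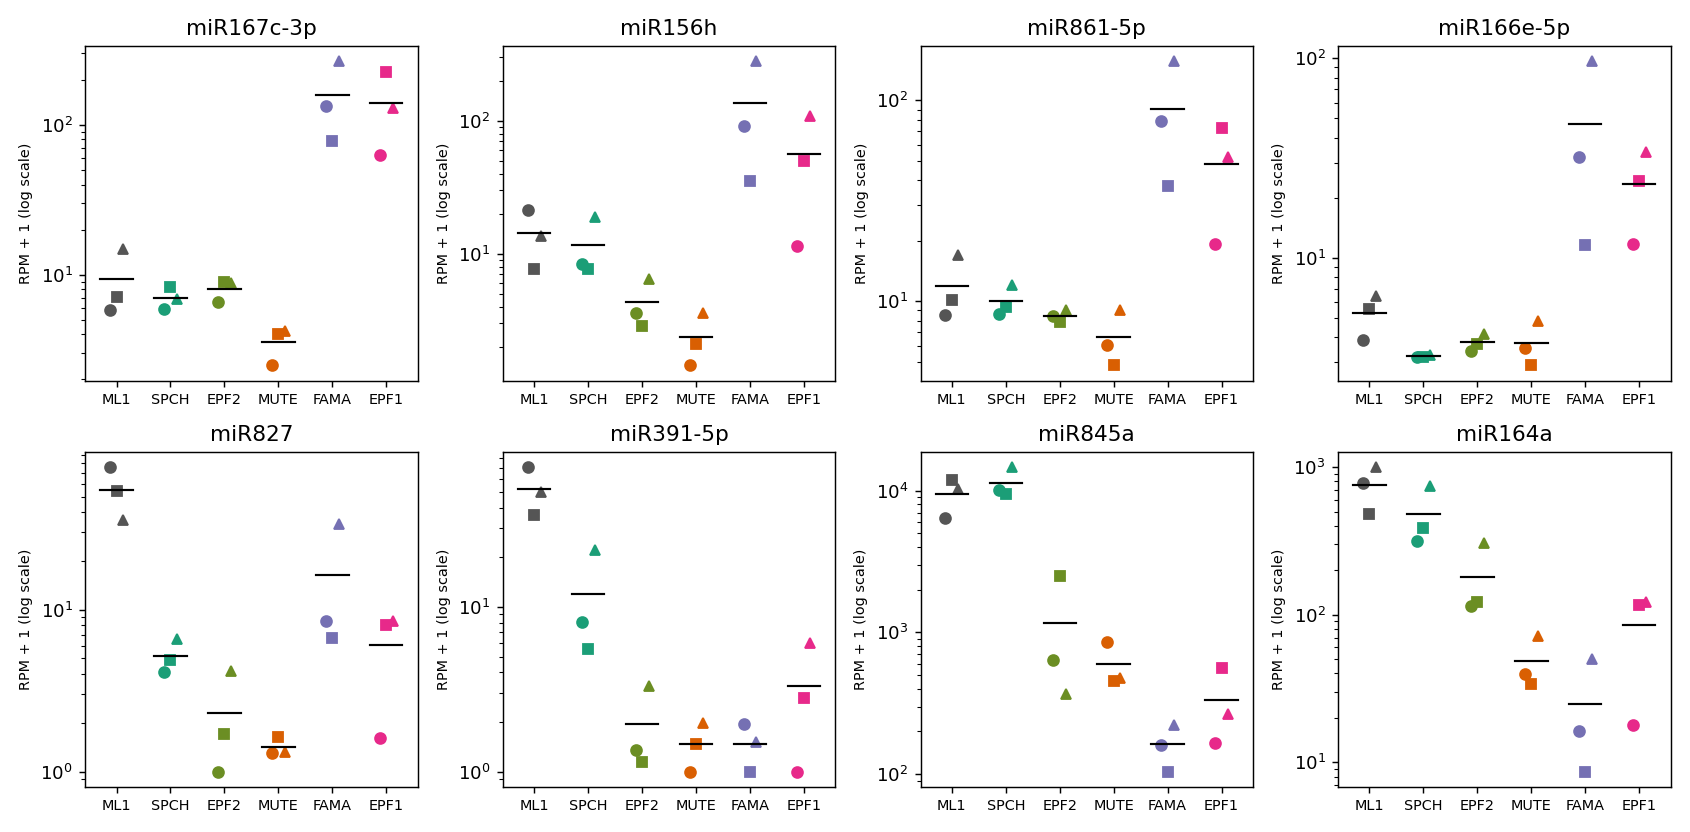
The panels plot 8 miRNAs (RPM + 1, log axis) in the 6 promoters; points are libraries and lines the mean of 3 libraries. miR167c-3p lies higher in FAMA (mean 159 RPM) and EPF1 (139 RPM) than in ML1 (8.30 RPM), whereas miR845a is lower in FAMA (161 RPM) than in ML1 (9519 RPM).

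Which miRNAs separated the lineage from the whole epidermis was asked by setting the mean of the 5 lineage promoters against ML1. miR391-5p (chromosome 5, 24293160 to 24293180, TAIR10) was lower in the lineage, at 3.03 ± 5.49 RPM (SD, n = 15) against 51.2 ± 17.2 in ML1 (SD, n = 3), a log2 change of -4.35 (SE 0.501, limma adjusted p 4.3e-08). miR827 (chromosome 3, 22122811 to 22122831), which targets the phosphate regulator NLA, had 5.26 ± 8.10 RPM (SD, n = 15) against 54.1 ± 20.0 (SD, n = 3), or -3.78 (SE 0.557, limma adjusted p 6.7e-06). miR5642a (chromosome 3, 14197116 to 14197135) was higher, at 66.3 ± 56.2 RPM (SD, n = 15) against 7.42 ± 1.70 (SD, n = 3), or 2.60 (SE 0.639, limma adjusted p 0.00201). The other arm of the miR157a duplex, miR157a-3p, had 91.5 ± 69.7 RPM (SD, n = 15) against 20.9 ± 23.7 (SD, n = 3), and miR157b-3p, which shares its reads, moved with it (2.32 each). These directions held after median-ratio scaling, with -3.53 for miR391-5p, -2.80 for miR827, 3.63 for miR5642a and 3.38 for miR157a-3p.

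Across the 273 rows, limma called 105 lower and 10 higher in the lineage (144 rows at an unadjusted p under 0.05). The median log2 change of all tested miRNAs was -0.78, and the median-ratio factors differed by -1.18 between the sides. After median-ratio scaling 60 were lower and 47 higher, and limma called 60 lower and 10 higher under both scalings. edgeR called 107 lower and 9 higher, and 71 lower and 41 higher with TMM scaling. Further down in the lineage were miR845a (-3.62), miR319b (-3.56), miR8183 (-3.20), miR164a (-3.11), miR833a-5p (-3.06), miR164b-5p (-3.03), miR822-5p (-2.90) and miR472-3p (-2.82). These are means over the 5 lineage promoters. In SPCH the mean RPM of miR845a was above that of ML1, and limma called none of these rows in SPCH against ML1. miR319 targets TCP transcription factors of leaf growth, miR164 targets NAC genes such as CUC2, and miR472 targets resistance genes. Higher were miR5642b (2.28), miR156d-3p (1.99), miR156b-3p (1.85), miR165a-5p (1.78), miR156a-3p (1.58), miR861-3p (1.03) and miR8176 (0.97). miR156b-3p (chromosome 4, 15075004 to 15075026) had 955 ± 620 RPM in the lineage (SD, n = 15) and 292 ± 290 in ML1 (SD, n = 3), and was past the threshold in limma (adjusted p 0.0107) but not in edgeR (adjusted p 0.0556). miR165a-5p (chromosome 1, 79010 to 79030) had 21.6 ± 12.1 RPM (SD, n = 15) against 5.09 ± 2.25 (SD, n = 3). All these directions were the same after scaling. The mean log2 change over all tested rows of a family was -0.32 for the family of miR157a-3p and miR157b-3p and -0.83 for that of miR165a-5p. The lineage libraries also held more reads of tRNA and chloroplast rows, so each call was made between libraries of unlike composition.

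**Figure D3:**
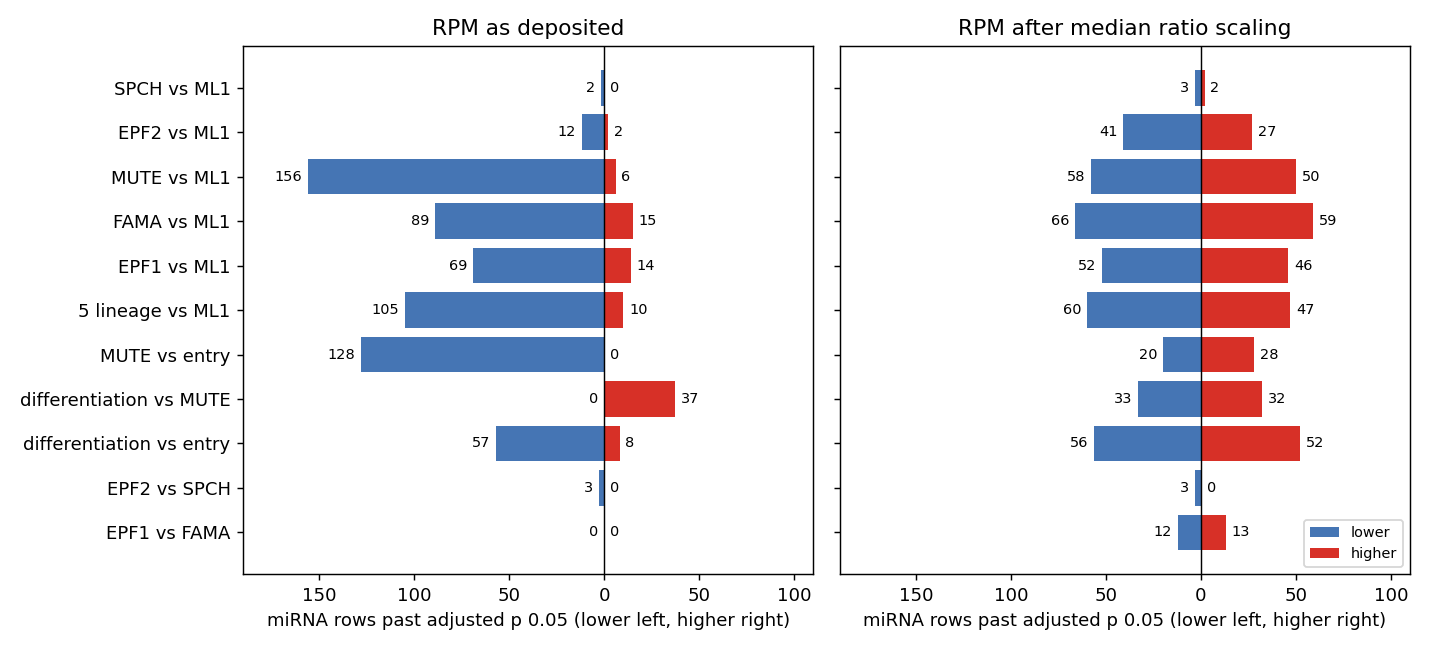
Bars count the miRNA rows called by limma (adjusted p under 0.05, of 273 tested) as lower (left) or higher (right) in each comparison, for RPM as deposited and after median-ratio scaling. Against ML1, MUTE has 156 rows lower and 6 higher in RPM, and 58 lower and 50 higher after scaling.

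Among the lists of miRNA families set before the data were examined, the phosphate and sulfate list (miR395, miR399, miR778, miR827 and miR2111) had all 12 tested rows lower in the lineage, over all rows and adjusted over the list alone, with a median log2 change of -2.11. These were rows of 3 families (miR395, miR399 and miR827), since no row of miR778 or miR2111 was tested. Rows of a family can share reads, so the 12 rows were not independent. After median-ratio scaling 9 of the 12 were lower. miR399b in this list, which targets the ubiquitin-conjugating gene PHO2, changed by -2.59 (limma adjusted p 0.00145). limma's camera test placed the list below the other miRNAs (adjusted p 8.8e-04). The phloem list (miR395, miR398, miR399 and miR2111, the last with no row tested) shares rows with it. Camera placed it likewise (adjusted p 0.00196), with 13 of 16 rows lower, 14 adjusted over the list alone. With an estimated correlation both adjusted p values were 0.936. Not called in this comparison were the conserved families (56 of 119 rows lower and 6 higher, camera adjusted p 0.438), the other families (49 of 154 lower and 4 higher, 0.438) and the leaf development list (32 of 68 lower and 6 higher, 0.735). Nor were the auxin list (4 of 19 lower, 1 adjusted over the list alone, camera adjusted p 0.438), the copper list (3 of 10 lower, 0.438), the small RNA machinery list (5 of 11 lower, 0.577), the triggers of secondary siRNA (8 of 16 lower, 0.438) and the miRNAs bound by AGO7 or AGO10 (9 of 17 lower and 1 higher, 0.538). Scaled by the median ratio, the rows lower and higher were 1 and 6 in the auxin list, 2 and 7 in the AGO7 and AGO10 list and 0 and 2 in the machinery list, so these counts turned. They were 33 and 25 in the conserved families, 27 and 22 in the other families, 19 and 16 in leaf development, 3 and 1 in copper, 5 and 3 in the triggers and 10 and 0 in phloem. Camera weighs a list against the remaining rows, and the auxin, leaf development, AGO7 and AGO10, and other-family lists ranked above them although their medians were negative. The MYB list had 2 tested rows and was not tested. Regrouped libraries often gave as many list calls as the real groups, so chance was not excluded for the lists as a set. As RPM, 0 of the 18 list calls held with an estimated correlation, and after median-ratio scaling 2 did, in SPCH against ML1.

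For SPCH against ML1, the question was what sets early lineage cells apart from the epidermis. miR827 fell to 4.20 ± 1.29 RPM in SPCH from 54.1 ± 20.0 in ML1 (SD, n = 3 each), a log2 change of -3.37 (SE 0.719, limma adjusted p 0.00567; -2.97 after scaling). miR826a changed by -2.11 (SE 0.328, limma adjusted p 5.7e-05; -1.49 after scaling), a size that the added 1 RPM limits, since few SPCH reads fell on this row. These were the only calls of 273 (21 at an unadjusted p under 0.05), and edgeR called 0 rows (adjusted p 0.113 for both), or 2 lower and 1 higher with TMM scaling. After median-ratio scaling limma called 3 lower and 2 higher. The median change of all rows was -0.25. Camera placed 3 lists lower, with an adjusted p of 2.2e-06 for the phosphate and sulfate list (median -1.01; 1 of 12 rows lower, 4 adjusted over the list alone). The phloem list had the same camera adjusted p of 2.2e-06 (0 of 16 rows lower, 3 adjusted over the list alone), and the copper list had 0.00278 (median -0.98; 0 of 10 rows called in either way of adjusting). The estimated correlation gave an adjusted p of 0.404 for the phosphate and phloem lists and 0.663 for copper, or 0.0204 for the first 2 lists and 0.0689 for copper after median-ratio scaling.

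EPF2, the other entry promoter, was compared with ML1 in the same way. miR391-5p fell to 0.941 ± 1.21 RPM from 51.2 ± 17.2 (SD, n = 3 each, log2 -4.87, SE 0.647, limma adjusted p 2.3e-06) and miR827 to 1.29 ± 1.66 from 54.1 ± 20.0 (-4.77, limma adjusted p 1.0e-05). The added 1 RPM limits both sizes, since few EPF2 reads fell on these rows. miR8183 fell to 10.2 ± 2.18 RPM from 137 ± 11.7 (-3.64), miR845a to 1173 ± 1174 from 9519 ± 2763 (-3.46) and miR319b to 199 ± 172 from 1568 ± 1204 (-2.96). Higher were miR156b-3p, at 1260 ± 532 RPM against 292 ± 290 (2.48, SE 0.735, limma adjusted p 0.0364; 0.104 in edgeR), and miR156d-3p (chromosome 5, 3456643 to 3456665), at 7.69 ± 7.02 against 0.450 ± 0.539 (2.35). The miR156 major arm targets SPL transcription factors. limma called 12 rows lower and 2 higher (86 at an unadjusted p under 0.05), and 41 lower and 27 higher after median-ratio scaling. edgeR called 11 lower and 1 higher, or 45 lower and 31 higher with TMM scaling. The median change was -0.47. No list was called (lowest camera adjusted p 0.347).

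MUTE against ML1 asked the same of cells at commitment. miR827 had 0.416 ± 0.187 RPM in MUTE against 54.1 ± 20.0 in ML1 (SD, n = 3 each), a log2 change of -5.22 (SE 0.719, limma adjusted p 1.6e-06). The added 1 RPM limits this size, since few MUTE reads fell on the row, and other settings gave -6.92 to -2.35. miR163 (chromosome 1, 24884359 to 24884382), which targets methyltransferase genes, had 25.8 ± 9.06 RPM against 1095 ± 639 (-5.22, SE 0.894, limma adjusted p 4.7e-05). miR319c (chromosome 2, 17029870 to 17029890) had 220 ± 46.7 RPM against 7574 ± 3696 (-5.01, SE 0.655, limma adjusted p 8.0e-07), and miR391-5p (-5.14) and miR319b (-5.06) fell too. miR5642a rose to 132 ± 102 RPM from 7.42 ± 1.70 (3.41, SE 0.825, limma adjusted p 9.8e-04). miR157a-3p (chromosome 1, 24913205 to 24913225) rose to 109 ± 55.9 RPM from 20.9 ± 23.7 (2.77, limma adjusted p 0.00412), with miR5642b (3.07), miR157b-3p (2.76) and miR156d-3p (1.82). The median change of all rows was -1.82 and the median-ratio factors differed by -2.38. limma called 156 lower and 6 higher in RPM (168 at an unadjusted p under 0.05), 58 lower and 50 higher after scaling, and 58 lower and 6 higher under both. edgeR gave 158 lower and 6 higher, or 61 lower and 39 higher with TMM scaling. After scaling, miR319c was at -2.63, miR163 at -2.88 and miR5642a at 5.61. Averaged over the tested rows of a family, the log2 change was -0.45 for the family of miR157a-3p and miR157b-3p and -0.66 for that of miR156d-3p. The phosphate and sulfate list had all 12 rows lower (median -2.82) but was not called (camera adjusted p 0.0511), and after scaling 2 of 12 were lower (median -0.58; 0.172).

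FAMA against ML1 addressed cells in differentiation. The other arm of the miR167c duplex, miR167c-3p (chromosome 3, 1306630 to 1306652), rose to 159 ± 96.9 RPM in FAMA from 8.30 ± 4.95 in ML1 (SD, n = 3 each), a log2 change of 4.05 (SE 0.725, limma adjusted p 7.5e-05; 5.29 after scaling). miR156h (chromosome 5, 22597087 to 22597106) rose to 135 ± 128 RPM from 13.2 ± 6.82 (2.89, SE 0.824, limma adjusted p 0.00481), whereas the tested rows of its family averaged -0.29. Both arms of miR861 rose by 2.77, with miR861-5p (chromosome 3, 17838223 to 17838243) at 89.9 ± 60.5 RPM against 10.9 ± 4.43, and miR5642a rose by 2.95. miR845a (chromosome 4, 12217457 to 12217477) fell to 161 ± 59.1 RPM from 9519 ± 2763 (-5.90, SE 0.707, limma adjusted p 2.2e-07). miR164a (chromosome 2, 19520770 to 19520790) fell to 23.9 ± 21.9 RPM from 751 ± 260 (-5.23, SE 0.785, limma adjusted p 7.2e-06), with miR391-5p (-5.14), miR164b-5p (-5.13) and miR164c-5p (-4.73). Scaled changes were -4.48 for miR845a and -3.86 for miR164a. The counts were 89 lower and 15 higher in limma (137 at an unadjusted p under 0.05; median change -0.95), 66 lower and 59 higher after scaling, and 66 lower and 15 higher under both. edgeR called 78 lower and 16 higher, or 61 lower and 67 higher with TMM scaling. All 12 phosphate and sulfate rows were lower, also adjusted over the list alone (median -3.53; camera adjusted p 1.5e-04), as were 13 of 16 phloem rows (0.00262; 11 lower and 3 higher after scaling). The auxin list ranked higher (median 0.68; 2 of 19 rows lower and 2 higher, 1 and 1 adjusted over the list alone; camera adjusted p 0.00501), and after scaling 0 were lower and 10 higher (median 1.11). The miRNAs bound by AGO7 or AGO10 were called only after scaling (camera adjusted p 0.00735), and not with an estimated correlation (0.488 after scaling). As RPM, the adjusted p of the 3 other lists was 0.918 with an estimated correlation.

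In EPF1 against ML1, miR167c-3p rose to 139 ± 81.3 RPM from 8.30 ± 4.95 (SD, n = 3 each; log2 3.85, SE 0.725, limma adjusted p 4.3e-04). The other arm of the miR166e duplex, miR166e-5p (chromosome 5, 16775636 to 16775656), rose to 22.4 ± 11.2 RPM from 4.28 ± 1.29 (2.04, limma adjusted p 0.0247), and miR5642a (2.75), miR156d-3p (2.29) and miR5642b (2.17) were higher as well, the last without a call in 13 of 37 other settings. miR845a fell to 330 ± 205 RPM from 9519 ± 2763 (-4.98, SE 0.707, limma adjusted p 9.0e-06), miR164a to 84.5 ± 58.6 from 751 ± 260 (-3.50, limma adjusted p 0.00306) and miR827 to 5.08 ± 3.87 from 54.1 ± 20.0 (-3.45). miR391-5p (-4.29) and miR319b (-3.79) were lower too. All named rows kept their direction after scaling (4.80 for miR167c-3p, -3.86 for miR845a), but the tested rows of the family of miR166e-5p averaged -0.43. limma called 69 lower and 14 higher (105 at an unadjusted p under 0.05; median change -0.74), 52 lower and 46 higher after scaling, and 52 lower and 14 higher under both. edgeR called 28 lower and 11 higher, or 69 lower and 34 higher with TMM scaling. The phosphate and sulfate list had 12 of 12 rows lower, also adjusted over the list alone (median -2.41; camera adjusted p 6.4e-04), and the phloem list 13 of 16 (0.00242). After scaling 9 and 10 rows of these lists were lower. With an estimated correlation the adjusted p was 0.931 for both.

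Stages were compared next. Between commitment (MUTE) and entry (the mean of SPCH and EPF2), miR319c had 220 ± 46.7 RPM (SD, n = 3) against 3501 ± 2253 (SD, n = 6), a log2 change of -3.69 (SE 0.568, limma adjusted p 4.8e-05). miR394a, which targets the F-box gene LCR, had 7.89 ± 2.55 RPM (SD, n = 3) against 138 ± 104 (SD, n = 6), or -3.65 (SE 0.725, limma adjusted p 6.6e-04), and miR394b-5p changed by -3.61. miR823, which targets the DNA methyltransferase gene CMT3, had 7.17 ± 1.53 RPM (SD, n = 3) against 111 ± 71.5 (SD, n = 6), or -3.52 (SE 0.755, limma adjusted p 0.00101), and miR447a.2-3p changed by -3.45. After scaling these were -1.81 for miR319c, -1.88 for miR394a, -1.84 for miR394b-5p, -1.76 for miR823 and -1.66 for miR447a.2-3p. limma called 128 lower and 0 higher (170 at an unadjusted p under 0.05; median change -1.39), but 20 lower and 28 higher after median-ratio scaling, and 20 lower and 0 higher under both. edgeR called 148 lower and 2 higher, or 18 lower and 14 higher with TMM scaling. The lowest camera adjusted p of a list was 0.422.

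From commitment to differentiation (the mean of FAMA and EPF1), miR167c-3p rose to 149 ± 80.7 RPM (SD, n = 6) from 2.56 ± 0.942 (SD, n = 3), a log2 change of 5.24 (SE 0.628, limma adjusted p 2.1e-07; 4.43 after scaling). miR163 rose to 1179 ± 1140 RPM (SD, n = 6) from 25.8 ± 9.06 (SD, n = 3), or 4.84 (SE 0.774, limma adjusted p 2.0e-05; 3.76 after scaling). miR156h rose to 95.1 ± 97.0 RPM (SD, n = 6) from 1.37 ± 1.09 (SD, n = 3), or 4.80 (4.23 after scaling), miR5012 by 4.55 (3.62 after scaling) and miR319c by 4.28 (3.17 after scaling). limma called 0 lower and 37 higher (85 at an unadjusted p under 0.05; median change 0.58), 33 lower and 32 higher after median-ratio scaling, and 0 lower and 27 higher under both. edgeR called 0 lower and 56 higher, or 20 lower and 25 higher with TMM scaling. Regrouped libraries gave as many calls as the real groups often enough that chance was not excluded for this count in RPM, nor for either count when regrouped only within replicate number.

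The same comparison called 6 lists at the preset correlation, each with an adjusted p of 0.722 at an estimated one. Camera ranked the auxin list higher (median 1.55; 6 of 19 rows higher, 12 adjusted over the list alone; adjusted p 0.00179), with miR167c-5p at 2.91. The miRNAs bound by AGO7 or AGO10 were higher (11 of 17 rows, also adjusted over the list alone; camera adjusted p 0.00179), with miR166e-5p at 2.85 and miR390a-3p at 2.74. The copper list was higher (median 1.49; 3 of 10 rows, 6 adjusted over the list alone; camera adjusted p 0.0211), with miR408-5p at 3.02 and miR408-3p at 2.54. The small RNA machinery list was higher (median 1.52; 4 of 11 rows, 8 adjusted over the list alone; camera adjusted p 0.0443), with miR168a-5p, which targets AGO1 itself, at 2.94. The phosphate and sulfate list ranked lower (camera adjusted p 0.00272) with a median of -0.15 and a mean of 0.02, so its mean and its test differed in sign, and miR827 was the 1 row of its 12 that was higher, in both ways of adjusting. The phloem list ranked lower (camera adjusted p 0.0477) with a median of -0.11 and a mean of 0.32, so that these differed in sign too, and 1 of its 16 rows, miR398a-3p, was higher (0 adjusted over the list alone). Median-ratio scaling changed the rows lower and higher to 1 and 5 in the auxin list, 2 and 4 in the AGO7 and AGO10 list, 0 and 3 in copper and 1 and 4 in the machinery list. In the phosphate and sulfate list they were 8 and 1 (10 and 1 adjusted over the list alone; median -1.20) and in phloem 8 and 0 (median -0.93), in the direction of the test. After this scaling the leaf development list was called too (camera adjusted p 0.0180, or 0.156 with an estimated correlation), while the machinery list (camera adjusted p 0.107) and the AGO7 and AGO10 list (0.0564) were not called. The machinery list also lost its call without MUTE replicate 1 (0.0516) or 2 (0.0778), FAMA replicate 3 (0.0525) and EPF1 replicate 2 (0.0763) or 3 (0.0507), and the copper list without EPF1 replicate 1 (0.0831). The phloem list lost its call without EPF2 replicate 3 (0.0509), MUTE replicate 2 (0.0778) or 3 (0.105), FAMA replicate 2 (0.0574) or 3 (0.0546) and EPF1 replicate 2 (0.129) or 3 (0.0596).

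Between differentiation and entry, both with 6 libraries, miR167c-3p rose to 149 ± 80.7 RPM from 6.56 ± 1.26 (SD, n = 6 each), a log2 change of 4.14 (SE 0.513, limma adjusted p 4.7e-07; 4.82 after scaling). miR156h rose to 95.1 ± 97.0 RPM from 6.98 ± 5.78 (3.23, limma adjusted p 1.3e-04), miR166e-5p to 34.1 ± 31.7 from 2.50 ± 0.386 (2.93, limma adjusted p 6.3e-05) and miR861-5p to 68.5 ± 48.0 from 8.25 ± 1.48 (2.64, limma adjusted p 2.0e-04). miR831-3p rose to 188 ± 115 RPM from 51.1 ± 34.5 (1.98) and miR861-3p by 1.82. miR845a fell to 246 ± 163 RPM from 6292 ± 5923 (-3.85, SE 0.500, limma adjusted p 7.0e-07; -3.07 after scaling). miR5024-3p fell to 4.17 ± 3.08 RPM from 36.5 ± 8.07 (-3.01), and miR173-3p (chromosome 3, 8236227 to 8236247), the other arm of the trigger of TAS1 and TAS2 siRNAs, to 2700 ± 1996 from 15475 ± 5114 (-2.74, SE 0.477, limma adjusted p 9.1e-05). miR164a (-2.96), miR164b-5p (-2.88), miR823 (-2.83), miR1888a (-2.82), miR3440b-3p (-2.78), miR164c-5p (-2.71) and miR399b (-2.68) were lower. All kept their direction after scaling, but the tested rows of the family of miR156h averaged -0.34.

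limma called 57 lower and 8 higher between these stages (101 at an unadjusted p under 0.05; median change -0.42), 56 lower and 52 higher after scaling, and 54 lower and 8 higher under both. edgeR called 47 lower and 12 higher, or 57 lower and 48 higher with TMM scaling. By regrouping the libraries without regard to replicate number, chance was not excluded for the count in RPM. Of the splits drawn, only the real one gave as many calls for the scaled count, and within replicate number for both counts. The other splits also mixed the promoters within a side, so this does not single out the stages. The phosphate and sulfate list ranked lower (median -2.03; 8 of 12 rows lower, 8 lower and 1 higher adjusted over the list alone; camera adjusted p 0.00898), with miR395b at -2.62. The auxin list ranked higher (median 0.05, or 0.73 after scaling; 1 of 19 rows lower and 2 higher, also adjusted over the list alone; 1 lower and 9 higher after scaling; camera adjusted p 0.00598), with miR167c-5p at 1.82. For both, the adjusted p was 0.928 with an estimated correlation. Copper (camera adjusted p 0.0303) and the miRNAs bound by AGO7 or AGO10 (0.0167) were called only after scaling. Neither call held with an estimated correlation (camera adjusted p 0.246 and 0.447 after scaling).

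Promoters labelled with the same stage were also set against each other. EPF2 differed from SPCH in miR845a, at 1173 ± 1174 RPM against 11412 ± 2774 (SD, n = 3 each; log2 -3.74, SE 0.707, limma adjusted p 0.00183). miR3932b-5p had 171 ± 90.8 RPM against 1228 ± 118 (-2.99, limma adjusted p 0.0209) and miR391-5p 0.941 ± 1.21 against 11.0 ± 9.00 (-2.54, limma adjusted p 0.0362). These were the 3 calls of 273 (27 at an unadjusted p under 0.05; median change -0.23), and after scaling limma again called 3 lower and 0 higher, whereas edgeR called 1 and edgeR with TMM scaling 0. Between EPF1 and FAMA limma called 0 of 273 rows (24 at an unadjusted p under 0.05, smallest adjusted p 0.115). The smallest p values were those of miR5023, at 0.519 ± 0.196 RPM against 7.07 ± 6.97 (-1.94), miR160b (chromosome 4, 9888986 to 9889006), at 63.1 ± 29.6 against 326 ± 187 (-2.30), and miR160a-5p, at 87.0 ± 47.2 against 356 ± 208 (-2.04; SD, n = 3 each). edgeR called 0 there, but 31 lower and 1 higher with TMM scaling, and limma called 12 lower and 13 higher after median-ratio scaling.

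miR824-5p (chromosome 4, 12625128 to 12625148), which targets AGL16 in the stomatal lineage, was followed in every comparison. It had 20.7 ± 14.3 RPM in ML1, 15.9 ± 9.36 in SPCH, 16.3 ± 13.9 in EPF2, 4.03 ± 1.89 in MUTE, 10.2 ± 6.45 in FAMA and 17.4 ± 17.8 in EPF1 (SD, n = 3 each). It was called only in MUTE against ML1 (log2 -1.98, SE 0.835, limma adjusted p 0.0397), where the sign turned after median-ratio scaling (0.10). Of 37 other settings each, it was called in 9 for MUTE against entry, 2 for differentiation against MUTE, and 1 each for EPF1 and the lineage against ML1. Against entry, MUTE had -1.63 (SE 0.723, limma adjusted p 0.0579; 0.01 after scaling). The lineage mean differed from ML1 by -0.88 (SE 0.647, limma adjusted p 0.289), and other settings gave -1.73 to 0.23. The other arm, miR824-3p, was called from commitment to differentiation, at 4.57 ± 3.01 RPM (SD, n = 6) against 0.716 ± 0.364 (SD, n = 3), or 1.52 (SE 0.490, limma adjusted p 0.0344; 0.95 after scaling).

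TAS loci give rise to trans-acting siRNAs and were read as small RNAs other than miRNAs. Their 8 rows summed to 93.3 ± 31.6 kRPM in ML1, 73.8 ± 8.24 in SPCH, 116 ± 63.0 in EPF2, 19.0 ± 2.93 in MUTE, 26.8 ± 16.8 in FAMA and 34.8 ± 16.9 in EPF1 (SD, n = 3 each). In MUTE against ML1, 6 of the 8 were lower (median -2.70, or -0.33 after scaling, with 2 lower and 1 higher), and in MUTE against entry all 8 were (median -2.52), and 2 after scaling. Between differentiation and entry 5 of 8 were lower (median -1.80), and 3 after scaling. TAS3, the source of siRNAs against ARF genes of auxin response, had 1469 ± 332 RPM in ML1, 1141 ± 392 in SPCH, 111 ± 21.4 in MUTE and 58.2 ± 37.4 in FAMA (SD, n = 3 each). TAS4 was the only TAS row called higher in EPF2 than in ML1, at 62.1 ± 28.6 RPM against 10.2 ± 3.34 (SD, n = 3 each; 2.44, limma adjusted p 0.0392).

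Reads on other genes were compared over 10670 rows. FAMA, the guard cell transcription factor, had 7.91 ± 6.93 RPM in differentiation and 0.233 ± 0.270 in entry (SD, n = 6 each), a log2 change of 2.50 (SE 0.262, limma adjusted p 1.8e-06). The myrosinase gene TGG1, expressed in guard cells, had 48.7 ± 47.3 RPM against 6.07 ± 2.22 (SD, n = 6 each; 2.39, limma adjusted p 0.00135), and CEL1 (2.12), MET4 (2.09) and the guard cell channel gene ALMT6 (2.06) were higher as well. SPL3, a target of miR156, fell to 0.213 ± 0.291 RPM from 7.84 ± 2.54 (SD, n = 6 each; -2.84, SE 0.321, limma adjusted p 3.7e-06). TAS3 changed by -3.43, the noncoding RNA AT4G26255 by -4.57, AT2G02835 by -2.69, and AAP5, within which miR5024 lies, by -2.88. limma called 440 lower and 522 higher (3900 at an unadjusted p under 0.05), of which 390 and 514 were not miRNAs, and 71 lower and 497 higher after median-ratio scaling. The scaling factors came from miRNA rows and were lower in differentiation, which raises every other row there. The scaled counts are thus no separate support for rises outside miRNAs.

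In the lineage against ML1, the serine carboxypeptidase gene SCPL54 (AT5G22960, chromosome 5, 7684014 to 7685052) fell to 1.33 ± 1.28 RPM (SD, n = 15) from 74.8 ± 14.2 (SD, n = 3), a log2 change of -5.18 (SE 0.350, limma adjusted p 6.0e-11). Lower too were AT4G26255 (-4.18), the pseudogene AT3G43828 (-3.63), AT3G30110, which contains miR8183 (-3.15), and AT1G78476, which contains miR833a (-3.06). The largest rises were all tRNA genes. AT1G56730 equalled AT1G56790 in mean, SD and change, as AT1G57450 did AT1G57510. These rows can hold the same reads and were not all separate rises. AT1G56730 and AT1G56790 had 121 ± 145 RPM (SD, n = 15) against 0.898 ± 0.155 (SD, n = 3; 5.09, SE 0.776, limma adjusted p 2.1e-04), and AT1G57450 (5.09), AT1G57510 (5.09) and AT1G17570 (4.97) were alike. limma called 907 lower and 2327 higher (4953 at an unadjusted p under 0.05), of which 817 and 2316 were not miRNAs, and 148 lower and 2543 higher after median-ratio scaling. Here too the factors came from miRNA rows and were lower in the lineage, so scaling by itself raises the other rows.

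Fragments of cell type markers were read in the same fit. In FAMA libraries the FAMA row had 13.3 ± 5.74 RPM, against 2.54 ± 0.855 in EPF1 and 0.478 ± 0.158 in ML1 (SD, n = 3 each; FAMA against ML1 3.20, limma adjusted p 2.3e-06). The receptor gene TMM had 4.32 ± 1.51 RPM in FAMA and 0.419 ± 0.458 in ML1 (SD, n = 3 each; 1.92, limma adjusted p 0.00151), and the guard cell channel gene KAT1 was higher by 1.45 (limma adjusted p 2.9e-04). Of 10 stomatal lineage markers 4 were tested, and 2 of these, FAMA and TMM, were higher in the lineage mean than in ML1. The FAMA row was not higher than in ML1 in SPCH (0.112 ± 0.098 RPM), EPF2 (0.355 ± 0.359) or MUTE (0.455 ± 0.445, SD, n = 3 each). Whether the FAMA promoter of the transgene adds reads to this row was not tested. All 8 mesophyll markers were higher in the lineage (median 2.14, or 3.22 after scaling), with RBCS1A at 113 ± 34.3 RPM in FAMA and 13.5 ± 3.37 in ML1 (SD, n = 3 each). The scaled median adds no separate support, because the factors from miRNA rows raise every other row in the lineage. The phloem marker SUC2 was higher in the lineage by 0.72, and 3 of 4 tested epidermal markers were higher (median 0.84), while 0 of 4 trichome markers had reads enough to be tested. Which cells such fragments came from was not measured.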

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

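The tests of the TAS loci and of the ratio of miRNA shares within a promoter were chosen only after the result was seen, as was the use of MUTE against entry to test stage, whereas the permutation tests of library composition and the search for libraries far from the others were set before.

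Entry and differentiation had 6 libraries each, and 9 measures of each were searched for a library far from the other five, which made 18 tests. In entry, EPF2 replicate 1 had 185 kRPM in the 8 TAS loci, and the next library had 103. In differentiation, EPF1 replicate 1 had 283 kRPM in rRNA rows, and the next library had 144. Chance alone would single out about 1 in 20 such tests, so 2 of 18 is close to what chance gives. EPF1 replicate 1 also had the lowest share of miRNA reads of its promoter (8.73%), and leaving it out changed the count of called miRNAs from commitment to differentiation from 37 to 100. The cause of either value was not tested, and groups of 3 libraries were too small to search.

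Most called miRNAs were lower than in ML1 as RPM, above all in MUTE. Background or yield that varies between libraries is a candidate explanation, since the share of miRNA reads differed 5.52 times between libraries of EPF1 (4.30 times in FAMA, 2.05 in EPF2, 1.47 in SPCH and 1.16 in ML1), within 1 promoter. The EPF1 ratio rests on replicate 1 (8.73%, against 36.1 and 48.2%). For MUTE, where the change was largest, this explanation stays open, because its libraries differed only 1.95 times and all were low (8.45 to 16.5%). A smaller share of all AGO1-bound small RNA in the library may also account for it, since the TAS loci, which give no miRNAs, were lower too (median log2 change of -2.70 in MUTE against ML1). The TAS loci were lower in FAMA (median -2.31) and EPF1 (-1.81) as well, but in EPF2 and SPCH their median change was -0.24 and -0.09, and the sum in EPF2 was 116 ± 63.0 kRPM against 93.3 ± 31.6 in ML1 (SD, n = 3 each), so a smaller AGO1-bound share is not supported there. The stage of the cells stays open, because MUTE lay below entry in the miRNA share (exact permutation p = 0.0119, the smallest possible) but yield was not measured apart from the promoter, so stage and yield cannot be told apart.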

How the results depend on the processing

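The tests with TMM scaling in edgeR, with median-ratio scaling and a pseudocount of 5, without the libraries numbered 17 to 22, and of the miRNA share within replicate number were chosen only after the result was seen; the other alternatives were set before. The reported counts were 157 miRNAs in the F test, 2 in SPCH, 14 in EPF2, 162 in MUTE, 104 in FAMA, 83 in EPF1 and 115 in the lineage mean, each against ML1. They were 128 in MUTE against entry, 37 in differentiation against MUTE, 65 in differentiation against entry, 3 in EPF2 against SPCH and 0 in EPF1 against FAMA (limma; 24 at an unadjusted p under 0.05). Over all rows they were 3234 for the lineage and 962 for differentiation against entry, and 18 lists were called. Only counts that moved by more than 1.5 times are given below, by alternative. The cause was not tested except where stated.

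Median-ratio scaling called 5 miRNAs in SPCH and 68 in EPF2 against ML1, 48 in MUTE against entry, 65 in differentiation against MUTE, 108 in differentiation against entry and 25 in EPF1 against FAMA, and 568 of all rows in differentiation against entry. Scaling to the miRNA total gave 4 in SPCH, 49 in EPF2 and 100 in MUTE against ML1, 44 in MUTE against entry, 89 in differentiation against MUTE, 114 in differentiation against entry, 33 in EPF1 against FAMA and 581 of all rows in differentiation against entry. Quantile normalization gave 8 in SPCH, 54 in EPF2 and 95 in MUTE against ML1, 47 in MUTE against entry, 63 in differentiation against MUTE, 99 in differentiation against entry, 6 in EPF2 against SPCH, 30 in EPF1 against FAMA and 1914 of all rows in differentiation against entry. Median-ratio scaling with a pseudocount of 5 gave 6 in SPCH, 74 in EPF2 and 102 in MUTE against ML1, 44 in MUTE against entry, 74 in differentiation against MUTE, 107 in differentiation against entry and 27 in EPF1 against FAMA. edgeR with TMM scaling gave 76 in EPF2 and 100 in MUTE against ML1, 32 in MUTE against entry, 105 in differentiation against entry, 0 in EPF2 against SPCH and 32 in EPF1 against FAMA. edgeR on the library totals gave 0 in SPCH (limma gave 21 at an unadjusted p under 0.05) and 39 in EPF1 against ML1, 56 in differentiation against MUTE and 1 in EPF2 against SPCH.

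Array weights, whose estimation stopped before its tolerance was met, gave 243 in the F test, 63 in SPCH and 117 in EPF2 against ML1, 208 in MUTE against entry, 124 in differentiation against MUTE and 39 in EPF2 against SPCH. Family means of the log2 values, which tested 121 families instead of 273 rows, gave 58 in the F test, 66 in MUTE, 43 in FAMA, 34 in EPF1 and 41 in the lineage against ML1, 62 in MUTE against entry, 19 in differentiation against MUTE, 29 in differentiation against entry and 0 in EPF2 against SPCH. A pseudocount of 5 gave 4 in SPCH and 31 in EPF2 against ML1, and no trend gave 22 in EPF2. A filter of at least 10 RPM, which tests fewer, gave 1 in SPCH against ML1, and 1277 and 246 of all rows for the lineage and for differentiation against entry. Without a filter 23 were called in differentiation against MUTE (397 tested) and 424 of all rows in differentiation against entry. Fitting only the groups compared gave 61 in EPF2 and 44 in EPF1 against ML1 and 7 in differentiation against MUTE. Adjusting over all rows gave 14 in differentiation against MUTE, 0 in EPF2 against SPCH and 1 in EPF1 against FAMA. Without the libraries numbered 17 to 22, which leaves 2 per promoter, the counts were 22 in SPCH, 104 in EPF2, 163 in FAMA and 125 in EPF1 against ML1, 19 in differentiation against MUTE and 260 of all rows in differentiation against entry.

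The runs of sample numbers as a replicate block gave 6 in SPCH and 78 in EPF2 against ML1, 78 in differentiation against MUTE, 1 in EPF1 against FAMA and 1657 of all rows in differentiation against entry. Whether the runs are batches is not stated by the labels. Permuted within the runs, the miRNA share of differentiation against entry had an exact p of 0.0370 instead of 0.128, and that of differentiation against MUTE 0.111 instead of 0.167. Of 45 pairs of libraries in a run, 31 correlated above 0.1 after removal of the promoter means (range -0.470 to 0.609), and 7 of 18 libraries correlated best with a library of their own run. Of the 30 pairs without ML1, 28 were above 0.1 (lowest -0.035, and 0.286 to 0.609 in the third run), against 3 of the 15 pairs with ML1, so lineage libraries of a run deviated together more than these did with ML1. All 12 pairs between entry and differentiation were above 0.1 (0.138 to 0.609). With the block the 18 lists and 98 of 99 named miRNA results stayed on their side of the threshold.

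Leaving out each library in turn, counts ranged from 122 to 199 in the F test, 1 to 6 in SPCH, 8 to 66 in EPF2, 131 to 176 in MUTE, 84 to 132 in FAMA, 47 to 95 in EPF1 and 68 to 135 in the lineage, each against ML1. They ranged from 47 to 173 in MUTE against entry, 17 to 100 in differentiation against MUTE, 51 to 100 in differentiation against entry, 1 to 7 in EPF2 against SPCH and 0 to 1 in EPF1 against FAMA. All rows ranged from 1347 to 3932 for the lineage and from 257 to 2007 for differentiation against entry, and called lists from 16 to 22. Libraries of other promoters enter through the shared spread. SPCH against ML1 moved without ML1 replicate 1 (1), SPCH replicates 1 (1) and 3 (5) and EPF2 replicate 3 (6). EPF2 against ML1 moved without ML1 replicates 2 (8) and 3 (22), EPF2 replicates 2 (8) and 3 (66), FAMA replicates 2 (31) and 3 (51) and EPF1 replicates 1 (64) and 3 (36). EPF1 and the lineage against ML1 moved without ML1 replicates 1 (48 and 69) and 2 (47 and 68). MUTE against entry moved without MUTE replicates 1 (47) and 2 (52). Differentiation against MUTE moved without MUTE replicates 1 (18) and 2 (17), FAMA replicates 2 (64) and 3 (23) and EPF1 replicates 1 (100), 2 (22) and 3 (24). Differentiation against entry moved without FAMA replicate 3 (98) and EPF1 replicate 3 (100). EPF2 against SPCH moved without SPCH replicates 1 (1) and 3 (1), EPF2 replicate 2 (1) and EPF1 replicate 1 (7), and EPF1 against FAMA without FAMA replicate 2 (1). Over all rows the lineage moved without ML1 replicates 1 (1347), 2 (1470) and 3 (1895). Differentiation against entry over all rows moved without ML1 replicates 1 (584), 2 (559) and 3 (604), SPCH replicates 2 (559) and 3 (257) and EPF2 replicates 1 (442) and 3 (330). It also moved without FAMA replicates 1 (371), 2 (546) and 3 (2007) and EPF1 replicate 3 (1861).

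Of the named results, 99 were miRNAs, 39 other rows and 18 lists. With median-ratio scaling 98 of the 99 miRNA results either kept their call and direction or were uncalled both times. Among the uncalled, a change of sign was not counted. For example, miR824-5p in MUTE against entry changed sign. Of the 18 lists called at the preset correlation, camera called 0 with an estimated correlation as RPM, and tested on families 1 was. In SPCH against ML1 the phosphate and phloem lists were called with both median-ratio scaling and an estimated correlation (adjusted p 0.0204 each). Calls of named miRNAs were lost most often for miR391-5p in EPF2 against SPCH (17 of 37 settings), miR5642b in EPF1 against ML1 (13 of 37), miR824-5p in MUTE against ML1 (8 of 37, and the direction in 4 more; calls were gained in 9 of 37 in MUTE against entry) and miR156b-3p in EPF2 against ML1 (10 of 37). From commitment to differentiation the phloem list lost its call in 10 of 23 settings and the small RNA machinery list in 8 of 23. In MUTE against ML1, miR824-5p turned from -1.98 to 0.28 with the miRNA total, 0.10 with the median ratio, 0.013 with quantiles and 0.058 with the median ratio and a pseudocount of 5. Family means of the log2 values turned miR157a-3p and miR157b-3p to -0.45 and miR156d-3p to -0.66 in MUTE, miR156h to -0.29 in FAMA, and miR166e-5p to -0.43 in EPF1 against ML1. They turned miR157a-3p and miR157b-3p to -0.32 and miR165a-5p to -0.83 in the lineage, and miR156h to -0.34 in differentiation against entry. Such a mean gives every tested row of the family the same weight, whatever its reads. The depth allows up to 0.963 RPM for a row listed at 0, and the miRNAs under the filter were not tested.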

Other observations

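The tests of duplex arms and of the row upstream of MUTE were chosen only after the result was seen, as were the splits within replicate number, whereas the other regrouping of libraries was set before.

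Within miRNA duplexes, the arm with fewer reads was compared with the arm with more. In the lineage against ML1, limma called 30 of 64 duplexes with a higher ratio of minor to major arm and 2, those of miR167c and miR408, with a lower ratio. By promoter, 0 were higher in SPCH, 17 in EPF2, 28 in MUTE, 28 in FAMA and 24 in EPF1. In the lineage the log2 ratio was higher by 4.22 (SE 0.593) for miR157a, 3.93 (SE 0.361) for miR165a, 2.35 (SE 0.403) for miR166a, 2.31 (SE 0.391) for miR156a and 2.08 (SE 0.432) for miR168a.

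AGO1 itself, whose mRNA is the target of miR168, had 18884 ± 12417 RPM in FAMA, 3874 ± 198 in EPF2, 1365 ± 537 in MUTE and 1432 ± 90.7 in ML1 (SD, n = 3 each; FAMA against ML1 3.51, limma adjusted p 0.00206). The transgene carries AGO1 sequence, so reads of the transgene and of the endogenous gene are not separated in this row.

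The arm pattern was not limited to duplexes with a minor arm near the detection limit in ML1. Of the duplexes with a minor arm of at least 10 RPM in ML1, 51.4% (18 of 35) were higher in the lineage. Counted by family, 19 of 24 of these were higher (sign test p 0.00661). The set was picked on ML1 libraries, so that a rise in the lineage did not bring a duplex into it. However, the ratio adds 1 RPM to both arms, and most miRNA rows had fewer RPM in the lineage libraries. Minor arms of this set can lie near the limit there, so the detection limit stays open as part of the cause. A low share of miRNA reads in a library could go with the pattern. This was read from another set, the duplexes with a minor arm of at least 10 RPM on the mean of all 18 libraries. Over the 15 lineage libraries Spearman's rho was only -0.239 (permutation p = 0.388, bootstrap interval -0.760 to 0.313). Pearson's r was -0.377 (permutation p = 0.166), or -0.319 without the 2 libraries farthest from the median share. The stage of the cells that the promoter marks cannot be told apart from other differences between promoters, since EPF2 against SPCH, which share a stage, called 1 duplex (of miR166) and stage varies only with the promoter. Strand loading, turnover and carried-over duplexes were not measured.

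The row AT3G06110 (named DSPTP1B in the deposited values and MKP2 in the annotation, chromosome 3, 1843413 to 1845062), which lies 1379 bases upstream of MUTE (chromosome 3, 1846442 to 1848259), had 34.8 ± 7.74 RPM in MUTE (SD, n = 3). The lowest MUTE library was 74.4 times the highest library of any other promoter. Of 33852 rows, only this row was at least 5 times above every other library in all MUTE libraries, and 0 other rows passed that rule. Sequence carried with the MUTE promoter in the transgene stays open as a candidate explanation, since this rule is how the row was found and does not decide it. Reads shared with a copy elsewhere in the genome stay open too, because a copy with reads of its own would not pass the rule. No biological explanation was tested. The same rule gave 2 rows in ML1 (SCPL54 and miR826a), 1 in EPF2 (AT1G29830) and 0 in SPCH and in EPF1, and these were not tested further.

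Libraries were regrouped, without regard to replicate number, to see how often other splits called as many miRNAs. The other splits also mixed the promoters within a side, so differences between promoters alone could lower their counts. A low share therefore speaks against labels that carry nothing, but does not single out the comparison named. For the lineage against ML1, 1 of 100 splits, the real one, gave as many (115 called, highest other split 112, or 107 and 35 after median-ratio scaling). For MUTE against entry 1 of 84 splits, the real one, gave as many (128 called, highest other 76, or 48 and 18 scaled). The F test gave 1 of 100 (157 called, highest other 102). For differentiation against MUTE 6 of 84 splits gave as many (37 called, highest other 217), so chance was not excluded, whereas after scaling 2 of 84 did (65 and 77). For differentiation against entry 7 of 100 splits gave as many (65 called, highest other 153) and chance was not excluded, but after scaling 1 of 100 did (108 and 85). Over all rows the share was 1 of 100 for the lineage (3234 and 2548) and 4 of 100 for differentiation against entry (962 and 2471). As many lists as the 18 called came up in 40 of 100 splits (highest other 37), so chance was not excluded. Splits that called several times the real count, as in differentiation against MUTE, point to a structure of the libraries other than the promoter.

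These splits mix the replicate numbers, and lineage libraries of the same number deviated together in 28 of 30 pairs. Splits within replicate number, chosen after seeing the data, were therefore counted for 4 comparisons. They too mixed the promoters within a side. For differentiation against entry 1 of 100 such splits, the real one, gave as many calls in both scalings (65 called, highest other 63, or 108 and 76 scaled). For differentiation against MUTE 2 of 27 did (37 called, highest other 53; scaled 65 and 81), so chance was not excluded there, as RPM or scaled. The share was 1 of 100 for the lineage against ML1 (115 and 39, scaled 107 and 27). For MUTE against entry it was 1 of 27, the smallest possible there (128 and 53, scaled 48 and 26). The labels do not say whether libraries of the same number were handled together.

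With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. The real and highest other counts were 2 and 0 in SPCH, 14 and 5 in EPF2, 162 and 0 in MUTE, 104 and 0 in FAMA, and 83 and 2 in EPF1, each against ML1. They were 3 and 0 in EPF2 against SPCH, and 0 and 194 in EPF1 against FAMA (25 and 0 after scaling), where a split calling so many more than the real one points to a structure of the libraries. As many calls as the real split came from 1 of 10 splits in each of these but EPF1 against FAMA as RPM (10 of 10).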
